A study of Arabidopsis thaliana with 6 samples.

How the data were processed

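RNA-seq was run on 6 libraries of Arabidopsis seedlings, 3 of the Columbia wild type and 3 of line BP12-2, all from seedlings treated with rapamycin. Per the labels' protocols, total RNA was isolated with a plant RNeasy kit and libraries were made with standard Illumina protocols. The series design text in the labels names paired-end sequencing on an Illumina HiSeq, alignment with Bowtie to the TAIR9 genome, counting of reads per gene with HTSeq, and edgeR for differential expression. Tool versions, the counting mode and the strand setting are not given in the sources used here. The deposited values are whole-number counts per gene, not normalized, for 32313 gene codes, of which 8089 were 0 in every library. Totals per library ran from 6706610 to 17092773 counts, so the precision of low genes differs between libraries. The table holds 0 chloroplast or mitochondrial gene codes. Since strand use in counting is not stated, reads of overlapping genes cannot be told apart, and genes that share sequence with a copy are uncertain.

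Groups and replicate numbers came from the sample titles. Counts of every pair of libraries were compared by a chi-square over genes, and the smallest ratio of chi-square to degrees of freedom was 11.5, so no library was a repeat of another. Gene names and coordinates came from the TAIR10.1 annotation, which held 31786 of the gene codes; it is not the build the authors used, and no coordinates were converted.

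Genes were kept by the default filter of edgeR (filterByExpr, count minimum 10 and total minimum 15), which left 19436. Libraries were scaled by TMM, with factors between 0.972 and 1.021, and CPM values are TMM-scaled. The main test was the edgeR quasi-likelihood F test with genotype as its only term, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A standard error is the log2 fold change divided by the root of its F statistic. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

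Before the data were examined, 34 gene lists with 654 entries, the tests, the alternatives and a rule for the genes to be named were fixed. All entries matched the annotation, 627 by symbol and 27 by description. Lists were tested with camera on voom values with a preset correlation of 0.01, adjusted over the 34 lists, and members were counted over all genes tested and adjusted over the list alone. The rule named TOR and any TOR list member past the threshold, then the 12 largest positive and the 12 largest negative fold changes past the threshold with a mean of at least 5 CPM and no overlap between groups, and then per list up to 4 members past the threshold or, where none passed, up to 2 with the highest mean CPM. List members named because they passed adjusted over the list alone, and the clock genes other than GRP7 and CCA1, were chosen after their values were seen.

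The alternatives fixed at that point were RLE and upper-quartile factors, library totals, no filter and a minimum mean of 5 CPM, DESeq2, the edgeR exact test, limma voom, a replicate block, each library left out in turn, stricter thresholds, removal of ribosomal RNA genes, and camera with an estimated correlation or fry for lists. Alternatives added after seeing the data were a term marking BP12-2 replicate 1 and WT replicate 3, which differ from the other libraries in clock transcripts, the other 4 libraries alone, and offsets for GC content and exon length. The tests were run on simulated counts for the 19436 genes with 200 genes changed. Their spread came from the fit with the term for the marked libraries, with a coefficient of variation of 11.7% against 16.3% in the main fit. Without a simulated difference between the marked libraries and the rest, the counts were therefore less variable than the real ones. There the quasi-likelihood test for BP12-2 against WT recovered 63% of genes changed 2-fold and 92% of those changed 4-fold, with 10 false calls among 165. The exact test made 43 false calls among 221 and DESeq2 28 among 197. With such a difference simulated, the quasi-likelihood test recovered 39% and 83%, with 1 false call among 123. The exact test recovered 66% and 99%, with 12 false calls among 177, and DESeq2 67% and 94%, with 9 among 170.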

Results

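Messenger RNA was counted by RNA-seq in Arabidopsis thaliana seedlings of the Columbia wild type (WT) and of line BP12-2, which the labels describe as a knockdown line for TOR, the target of rapamycin kinase. BP12 lines carry the yeast FKBP12 protein, which lets rapamycin bind and inhibit the plant TOR kinase. Seedlings aged 15 days after germination had spent 3 days on medium of 0.5 MS strength with 10 µg/ml rapamycin, so the drug was present in both groups. Each group had 3 libraries, with total counts of 10322303, 6706610 and 17092773 for BP12-2 replicates 1 to 3 and of 7611017, 13544765 and 16371859 for WT replicates 1 to 3. Seedlings kept on the solvent control medium were not analysed here, and 1 BP12 line was used. A difference between BP12-2 and WT that exists without rapamycin therefore cannot be told apart from an effect of the drug on BP12-2. The comparison asks which transcripts differ between BP12-2 and WT when both are exposed to rapamycin. The labels do not say whether the libraries of a group came from separately grown seedlings, so p-values measure only the spread between these samples, which may be technical.

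The TOR transcript itself (AT1G50030, chromosome 1, 18522248 to 18539995 in the TAIR10.1 annotation, minus strand) was counted at 32.4, 27.8 and 32.6 CPM in BP12-2 replicates 1 to 3 and at 34.3, 35.9 and 38.5 CPM in WT replicates 1 to 3. The 3 BP12-2 values lay below the 3 WT values, with a log2 fold change of -0.22 ± 0.10 (SE, n = 3 per group). This difference did not pass the edgeR quasi-likelihood test (adjusted p = 0.292). RAPTOR1, the TOR partner protein, was at 99.1 ± 1.99 CPM in BP12-2 and 113 ± 3.66 in WT (SD, n = 3), and S6K1, a kinase that TOR phosphorylates, was at 128 ± 18.9 and 109 ± 11.7 CPM. Neither passed the edgeR test, and 0 of the 16 measured TOR signalling genes did, over all genes tested or adjusted over the list alone. With offsets for GC content and transcript length, an alternative chosen after seeing the data, the TOR log2 fold change was -0.11.

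With the edgeR quasi-likelihood test 13 genes passed between BP12-2 and WT under rapamycin, 12 lower and 1 higher in BP12-2. The split moved with the setting, with 398 higher and 443 lower by the edgeR exact test, 279 and 343 by DESeq2, and 32 higher and 24 lower without WT replicate 1. ERD5 (AT3G30775), which encodes proline dehydrogenase, an enzyme of proline breakdown, fell from 476 ± 32.4 CPM in WT to 69.8 ± 13.8 CPM in BP12-2 (SD, n = 3), a 6.84-fold reduction. SIP2 (AT3G57520), an alpha-galactosidase that acts on raffinose, fell from 282 ± 27.1 to 83.6 ± 17.5 CPM, and SUC1 (AT1G71880), a sucrose-proton symporter, from 212 ± 16.4 to 99.1 ± 10.4 CPM. The gene that rose was AT5G15780 of the Pollen Ole e 1 allergen and extensin family, from 155 ± 11.9 to 350 ± 54.0 CPM. It missed the threshold whichever library was left out (edgeR adjusted p from 0.0531 to 0.166), with log2 fold changes from 1.07 to 1.29.

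The 13 genes were among 19436 tested. The log2 fold change of ERD5 was -2.77 ± 0.16 (SE; edgeR adjusted p = 0.00361), that of SIP2 -1.76 ± 0.16 (adjusted p = 0.0390), that of SUC1 -1.10 ± 0.11 (adjusted p = 0.0390) and that of AT5G15780 1.18 ± 0.14 (adjusted p = 0.0489). The neighbouring genes AT5G23360 and AT5G23370, both of the GRAM domain family annotated as ABA-responsive-like, fell by 1.74 and by 1.15 on the log2 scale. HR4, a homolog of the RPW8 resistance protein, fell by 1.31, UGT76B1, a glycosyltransferase that acts on salicylic acid, by 0.78, and PMAT1, a malonyltransferase of phenolic glucosides, by 0.95 on the log2 scale. The cytochrome P450 gene CYP705A20 fell by 1.77, the lipid-transfer family gene AT4G12490 by 1.95, the AP2/ERF-type gene AT4G39780 by 0.87 and AT5G52882, which encodes a P-loop nucleoside triphosphate hydrolase, by 0.91. The adjusted p of these 9 genes lay between 0.0289 and 0.0390.

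In the TAIR10.1 annotation ERD5 spans 12448636 to 12451556 on the minus strand of chromosome 3 and SIP2 spans 21288742 to 21293171 on the minus strand of chromosome 3. SUC1 spans 27054030 to 27056464 on the plus strand of chromosome 1, and AT5G15780 spans 5144629 to 5146458 on the minus strand of chromosome 5. AT5G23360, at 7861737 to 7862746 on the plus strand, and AT5G23370, at 7863216 to 7864291 on the minus strand, lie side by side on chromosome 5. The exons of these 6 genes overlap no annotated exon of another counted gene. Overlap with introns or with genes that were not counted was not checked. AT4G12490 shares 6.8% of its 50-base words with AT4G12500, AT5G23360 shares 4.6% with other genes (2.5% with AT5G23350) and AT5G23370 shares 1.9% with AT5G23360, so part of the counts of these 3 genes is uncertain.

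The 3 BP12-2 values of all 13 genes lay outside the range of the 3 WT values, which is likely for genes picked by a test between these groups. Among all tested genes 24.3% were separated in this way, where 10% is expected per gene if the group labels did not matter. Genes are not independent of each other, so the gap between these shares is no test of the genotype. The count of 13 moved with the test and with single libraries: the edgeR exact test gave 841 genes, DESeq2 622, and the quasi-likelihood test 0 without BP12-2 replicate 3, 1 without BP12-2 replicate 2, 1 without WT replicate 2, 2 without WT replicate 3 and 56 (32 higher, 24 lower) without WT replicate 1. A term marking the 2 libraries that differed from the other 4 in circadian clock transcripts gave 992 genes, 489 higher and 503 lower. In those other 4 libraries alone 41 genes passed, 37 lower and 4 higher. Both alternatives were chosen after seeing the data. The marked pair holds 1 library per group and allows no test.

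**Figure D1:**
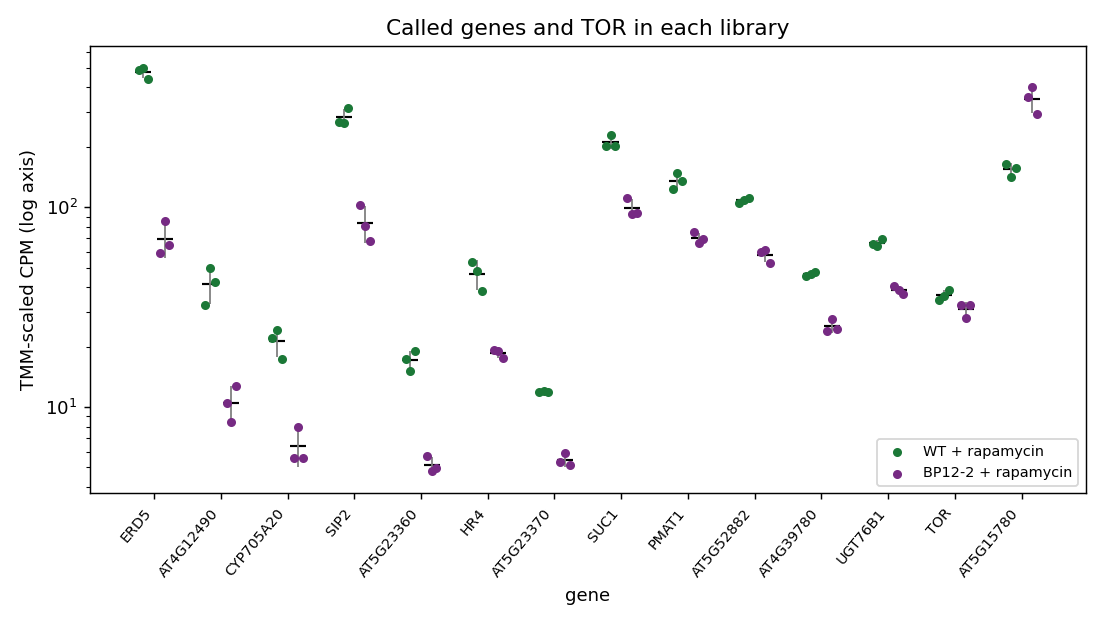
TMM-scaled CPM (log axis) of the 13 genes that passed the edgeR test and of TOR, with 1 point per library, green for WT and purple for BP12-2, a black bar at the mean and a grey line for the SD (n = 3). ERD5 is at 476 CPM in WT and 69.8 CPM in BP12-2, and AT5G15780 is the gene that is higher in BP12-2.

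Transcripts of the photosynthetic apparatus were higher in BP12-2 as groups, by small amounts, in a list test with a preset correlation. The test (camera, 2-sided) gave adjusted p = 1.90e-08 for photosystem subunits, 5.66e-06 for light-harvesting proteins and 4.03e-06 for the Calvin cycle, and adjusted p = 0.490 for each with an estimated correlation. All 23 photosystem subunit genes, all 21 light-harvesting genes and all 18 Calvin cycle genes had positive log2 fold changes, with medians of 0.30, 0.31 and 0.35. PSAK, a subunit of photosystem I, was at 426 ± 1.68 CPM in BP12-2 and 303 ± 7.92 in WT (SD, n = 3), and PSAF, the plastocyanin-docking subunit, at 3146 ± 433 and 2109 ± 72.5 CPM. LHCB6 was at 3567 ± 237 and 2679 ± 74.8 CPM, and the Rubisco small subunit gene RBCS3B at 4993 ± 392 and 3282 ± 488 CPM. Among the most abundant members, PSBO1 had a log2 fold change of 0.27 ± 0.15 (SE), CAB1 0.20 ± 0.20 and RBCS1A 0.42 ± 0.19.

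No member of the photosystem, light-harvesting and Calvin cycle lists passed over all genes tested, and 7, 4 and 4 members passed adjusted over the list alone, all of them higher. In the 4 libraries of one clock pattern the medians were 0.27, 0.23 and 0.32, and between the other 2 libraries 0.39, 0.40 and 0.35. Without BP12-2 replicate 1 the light-harvesting median was 0.19. Relative to the mean of all libraries on the log2 scale, the photosystem median was 0.35, 0.01 and 0.11 in BP12-2 replicates 1 to 3. It was -0.18, -0.17 and -0.08 in WT replicates 1 to 3. The light-harvesting medians were 0.34, -0.03 and 0.13 in BP12-2 and -0.21, -0.20 and -0.06 in WT. Those of the Calvin cycle were -0.01, 0.27 and 0.25 in BP12-2 and -0.05, -0.14 and -0.33 in WT. In each of these 3 lists the lowest BP12-2 library lay only slightly above the highest WT library. Chlorophyll synthesis genes had a median of 0.14 (camera adjusted p = 0.0181; adjusted p = 0.490 with an estimated correlation), and G4, the chlorophyll synthase gene, was the member that passed adjusted over the list alone, at 22.8 ± 0.87 against 15.4 ± 0.81 CPM. Without BP12-2 replicate 2 or WT replicate 1 the chlorophyll list did not pass (adjusted p = 0.0512 and 0.0986), with a median of 0.08 without BP12-2 replicate 2; its median was 0.22 in the 4 libraries of one clock pattern and 0.01 between the other 2. GUN5, its most abundant member, was at 4356 ± 330 and 4263 ± 921 CPM.

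Transcripts of wounding responses and of salicylate defence were lower in BP12-2 by camera with the preset correlation. The adjusted p was 4.55e-07 for wounding and touch and 2.60e-06 for salicylate defence, and adjusted p = 0.490 for both with an estimated correlation. All 15 measured wounding and touch genes had negative log2 fold changes (median -0.90), as did 14 of the 16 salicylate defence genes (median -0.86). WRKY33, a transcription factor of pathogen responses, was at 33.3 ± 6.99 CPM in BP12-2 and 57.2 ± 14.9 in WT (SD, n = 3), the zinc finger gene SZF1 at 38.8 ± 4.52 and 82.0 ± 35.1 CPM, and the calmodulin-like touch gene TCH3 at 25.6 ± 7.23 and 54.3 ± 15.8 CPM. WRKY70, a regulator of salicylate responses, was at 23.9 ± 7.39 and 61.5 ± 8.95 CPM, PBS3, an enzyme of salicylate synthesis, at 5.22 ± 2.44 and 13.3 ± 2.61 CPM, and the pathogenesis-related gene PR1 at 8.57 ± 2.66 and 18.3 ± 7.46 CPM.

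Adjusted over the list alone, 9 wounding genes and 6 salicylate genes were lower and none was higher, while 0 members passed over all genes tested. The wounding median was -0.97 in the 4 libraries of one clock pattern and -0.82 between the other 2 libraries, and the salicylate median was -1.29 and -0.32. WT replicate 2 stood apart from the other WT libraries for the wounding genes. Its list median was -0.12 relative to the mean of all libraries on the log2 scale, against 0.78 and 0.69 in WT replicates 1 and 3 and -0.29, -0.45 and -0.61 in BP12-2 replicates 1 to 3. The code in the count table's column names is L08 for the 3 BP12-2 libraries and L07 for the 3 WT libraries; its meaning is not given in the sources used here, and it cannot be told apart from the genotype.

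Flavonoid and anthocyanin genes had a median log2 fold change of -1.10 (camera adjusted p = 0.00703; adjusted p = 0.681 with an estimated correlation), and 7 of 16 members were lower adjusted over the list alone. WT replicate 2 stood apart from the other libraries here, with a list median 1.55 above the mean of all libraries on the log2 scale, against 0.23 and -0.02 in WT replicates 1 and 3. The anthocyanin enzyme gene DFR was at 15.4 ± 7.49 CPM in BP12-2 and 67.3 ± 66.6 in WT, LDOX at 30.1 ± 14.8 and 119 ± 104 CPM, and chalcone synthase (TT4) at 757 ± 157 and 1038 ± 557 CPM (SD, n = 3). Without WT replicate 2 the median was -0.41 (adjusted p = 0.0240), and without BP12-2 replicate 1 the list did not pass (adjusted p = 0.0735). The median was -1.31 in the 4 libraries of one clock pattern and -0.49 between the other 2.

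Ribosome assembly genes were slightly lower in BP12-2. Of 20 ribosome biogenesis genes 19 had negative log2 fold changes (median -0.28; camera adjusted p = 5.20e-05; adjusted p = 0.490 with an estimated correlation). The median was -0.16 in the 4 libraries of one clock pattern (adjusted p = 0.0139) and -0.46 between the other 2. Relative to the mean of all libraries, the list median was -0.31 in BP12-2 replicate 1, 0.03 and -0.07 in BP12-2 replicates 2 and 3, and 0.11 to 0.14 in WT. SWA1 and TOZ, nucleolar proteins of ribosomal RNA processing, were the 2 members lower adjusted over the list alone, SWA1 at 36.1 ± 0.93 CPM in BP12-2 and 47.7 ± 1.35 in WT and TOZ at 15.1 ± 1.39 and 22.7 ± 2.29 CPM (SD, n = 3). The 32 cytosolic ribosomal protein genes had a median of -0.09 (camera adjusted p = 0.0396; adjusted p = 0.814 with an estimated correlation), which turned to 0.04 without BP12-2 replicate 1 and to 0.03 in the 4 libraries of one clock pattern. The abundant member RP1, which encodes a protein of the large subunit, was at 572 ± 94.8 and 678 ± 38.6 CPM. That list also missed the threshold without WT replicate 1 or WT replicate 2 (adjusted p = 0.157 and 0.0979), and its median was -0.05 without WT replicate 1, -0.18 without BP12-2 replicate 2, -0.16 without BP12-2 replicate 3 and -0.33 between the other 2 libraries.

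The auxin response, root marker, secondary wall, and brassinosteroid and gibberellin synthesis lists were higher in BP12-2. The medians were 0.32 for 18 auxin response genes (camera adjusted p = 3.60e-04; adjusted p = 0.490 with an estimated correlation), 0.26 for 20 root markers (adjusted p = 2.04e-04; adjusted p = 0.567 with an estimated correlation) and 0.25 for 22 secondary wall and lignin genes (adjusted p = 0.00149; adjusted p = 0.567 with an estimated correlation). The brassinosteroid and gibberellin synthesis list had a median of 0.22 (camera adjusted p = 0.00858, and 0.490 with an estimated correlation). That list also holds a gibberellin-induced gene, GASA6, so its median does not measure synthesis enzymes alone. GH3.3, an auxin-conjugating enzyme gene, was at 29.2 ± 5.85 CPM in BP12-2 and 15.6 ± 2.19 in WT, the root hair expansin EXPA7 at 22.8 ± 3.19 and 13.3 ± 2.98 CPM, and the gibberellin-induced gene GASA6 at 99.8 ± 46.8 and 41.4 ± 10.8 CPM (SD, n = 3). Adjusted over the list alone, 1 member of the auxin list, 1 of the root list and 3 of the hormone synthesis list were higher. Of the secondary wall genes 0 passed, and PAL1, the most abundant of them, was at 761 ± 80.8 and 737 ± 186 CPM. Without WT replicate 3 the secondary wall median was 0.11 and the list did not pass (adjusted p = 0.0661). Without WT replicate 1 the root marker median was 0.56 and the hormone synthesis median 0.34. Between the 2 libraries of the other clock pattern the root marker median was 0.44. Relative to the mean of all libraries, the root marker median of WT replicate 1 was 0.20, at the level of BP12-2 (0.14 to 0.19), against -0.45 and -0.35 in WT replicates 2 and 3.

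Expansins and primary wall genes went both ways. Adjusted over the list alone, 6 of 18 were higher, all of them expansins, and XTH9, a xyloglucan-modifying enzyme gene, was lower. EXPA1 was at 255 ± 32.1 CPM in BP12-2 and 140 ± 12.7 in WT, EXPA8 at 81.2 ± 33.8 and 26.9 ± 10.2 CPM, and the cellulose synthase gene CESA1 at 398 ± 8.23 and 429 ± 37.5 CPM (SD, n = 3). The list did not pass camera (adjusted p = 0.153) and passed fry, which tests whether the genes move on balance in a given direction (adjusted p = 0.00366).

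The remaining 4 lists past camera held small shifts that depended on single libraries or on few genes. Senescence and chlorophyll breakdown genes had a median of -0.28 (adjusted p = 0.00927; adjusted p = 0.490 with an estimated correlation) and missed the threshold without BP12-2 replicate 3 (adjusted p = 0.139); the median was -0.14 between the 2 libraries of the other clock pattern. BP12-2 replicate 1, at 0.18 relative to the mean of all libraries, lay at the level of WT (0.12 to 0.18), and SAG21 was at 77.0 ± 15.5 and 101 ± 19.8 CPM. Glucosinolate synthesis genes had a median of -0.18 (adjusted p = 0.0288; adjusted p = 0.705 with an estimated correlation), with CYP79B2 and MAM3 lower and MYB34 higher adjusted over the list alone. That list did not pass without BP12-2 replicate 1 (median -0.09, adjusted p = 0.228), BP12-2 replicate 2 (0.0512), WT replicate 1 (0.0844) or WT replicate 2 (median -0.10, adjusted p = 0.130). Phosphate starvation genes had a median of -0.36 (adjusted p = 0.0288; adjusted p = 0.707 with an estimated correlation), which was -0.02 without WT replicate 2 (adjusted p = 0.903), and the list also missed the threshold without BP12-2 replicate 2 (0.0983) or BP12-2 replicate 3 (0.218; median -0.23). The phosphate median was -0.54 without WT replicate 3, -0.71 in the 4 libraries of one clock pattern (adjusted p = 4.07e-08) and turned to 0.44 between the other 2. WT replicate 2 was at 0.60 relative to the mean of all libraries, WT replicates 1 and 3 at 0.04 and -0.24, and BP12-2 replicates 1 to 3 at 0.19, -0.28 and -0.43. SQD1 was at 220 ± 24.9 and 274 ± 57.0 CPM. Autophagy genes had a median of 0.16 (adjusted p = 0.0396; adjusted p = 0.681 with an estimated correlation) and did not pass without BP12-2 replicate 1 (0.278; median 0.10), BP12-2 replicate 2 (0.0599) or WT replicate 2 (0.205), nor in the 4 libraries of one clock pattern (0.109), while the median was 0.26 without BP12-2 replicate 3; NBR1, a cargo receptor, was at 304 ± 75.8 and 314 ± 54.0 CPM.

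**Figure D2:**
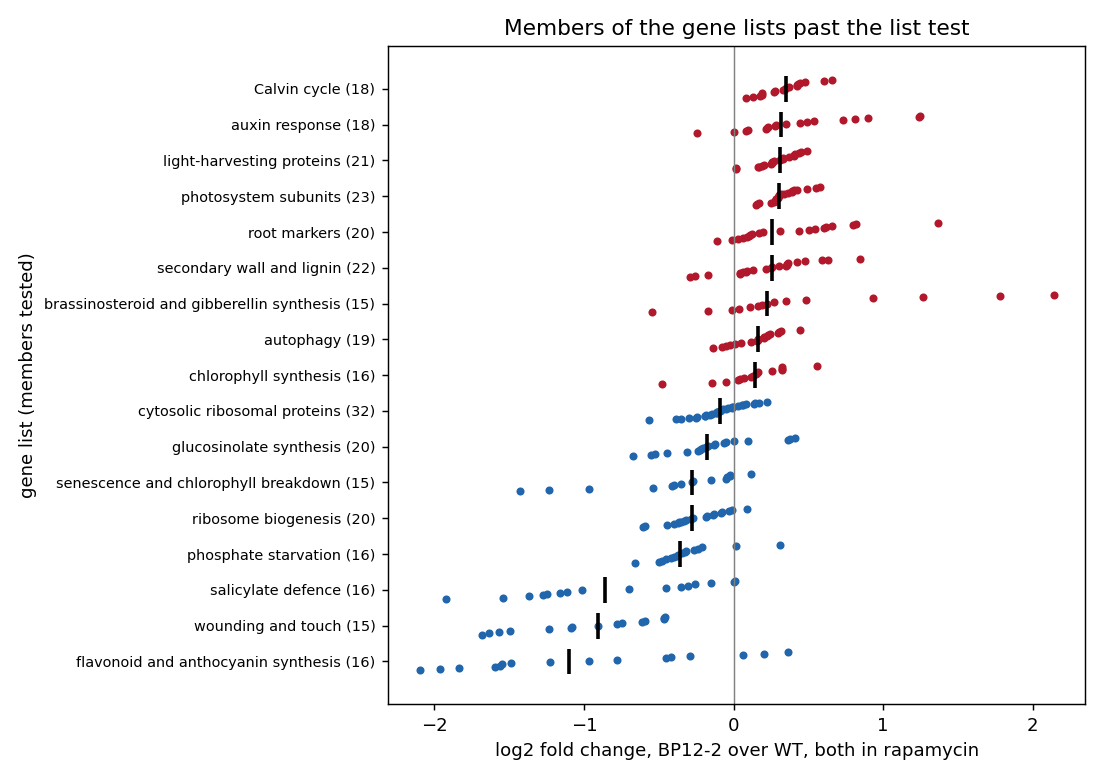
Log2 fold change of BP12-2 over WT for each measured member of the 17 lists past camera with the preset correlation, red where the list test points up and blue where it points down, with a black bar at the list median and the number of members in brackets. All 15 wounding and touch genes lie below 0 and all 23 photosystem subunit genes above 0.

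The other 17 lists did not pass camera. Cell division had a median of 0.20 (camera adjusted p = 0.0810), with CYCD3;2 at 69.2 ± 5.79 and 74.0 ± 9.04 CPM in BP12-2 and WT, and DNA replication 0.12 (adjusted p = 0.214), with TSO2 at 116 ± 24.9 and 111 ± 7.63 CPM. Energy starvation markers had a median of -0.03 (adjusted p = 0.503), with GDH2 at 162 ± 42.1 and 257 ± 40.2 CPM, and starch and sugar metabolism -0.23 (adjusted p = 0.0573), with BAM1 at 276 ± 27.1 and 311 ± 95.2 CPM. The ethylene pathway had a median of -0.11 (adjusted p = 0.0810), with ACS6, ACS7 and EBF2 lower adjusted over the list alone, and the jasmonate pathway -0.19 (adjusted p = 0.118), with LOX2 at 790 ± 187 and 1276 ± 612 CPM. Without BP12-2 replicate 1 these 6 lists passed, with adjusted p of 0.00512, 0.00394, 0.00955, 0.00794, 0.0116 and 0.00872 in the order given. Camera with a library left out was run with the preset correlation only. With an estimated correlation and all libraries, it gave adjusted p of 0.707, 0.814, 0.908, 0.567, 0.567 and 0.705 for these lists. Without WT replicate 1 the starch (adjusted p = 0.0210), jasmonate (0.0418) and seed storage lists (0.0418) passed, and without WT replicate 3 the heat shock list (0.0369). The starch list also passed with the replicate block (adjusted p = 0.0442), the clock-pattern term (0.0235; adjusted p = 0.582 with an estimated correlation) and in the 4 libraries of one clock pattern (0.00421). In those 4 libraries cell division (0.0173), DNA replication (0.0139), ethylene (0.0222) and jasmonate (0.0226) passed as well, again with the preset correlation only. With a library left out, the medians reached 0.30, 0.24, -0.30, -0.32, -0.25 and -0.42 without BP12-2 replicate 1, in the order given. At the other end, cell division was at 0.07 and energy starvation at 0.14 without BP12-2 replicate 3. DNA replication was at 0.02 and jasmonate at -0.12 without BP12-2 replicate 2, starch at -0.11 without WT replicate 2, and ethylene at -0.04 without BP12-2 replicate 3 or WT replicate 3.

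Cytokinin response genes had a median of -0.09 (camera adjusted p = 0.464), with the response factor genes CRF2, CRF5 and CRF6 lower adjusted over the list alone; CRF6 was at 16.2 ± 2.25 CPM in BP12-2 and 32.7 ± 6.19 in WT (SD, n = 3). The medians were 0.04 for abscisic acid response (adjusted p = 0.794), -0.05 for heat shock and protein folding (0.794), -0.27 for iron homeostasis (0.715), 0.19 for nitrogen assimilation (0.995) and -0.06 for TOR signalling (0.503). The iron and abscisic acid examples were OPT3, at 225 ± 24.5 and 380 ± 157 CPM, and COR47, at 484 ± 49.2 and 366 ± 131 CPM, and the nitrate reductase gene NIA2 was at 1620 ± 176 and 2031 ± 145 CPM. The chaperone gene HSC70-1 was at 3954 ± 710 and 4049 ± 670 CPM. Camera pointed up for heat shock and down for abscisic acid, against the sign of each median. With a library left out, the iron median ran from -0.44 (without WT replicate 1 or 2) to 0.27 (without WT replicate 3). The abscisic acid median ran from -0.18 (without BP12-2 replicate 1) to 0.14 (without WT replicate 2), and the heat shock median from -0.23 (without WT replicate 3) to 0.15 (without WT replicate 1). The nitrogen median lay between 0.03 (without WT replicate 3) and 0.13 (without BP12-2 replicate 2). The cytokinin median ran from -0.18 (without BP12-2 replicate 3) to 0.04 (without WT replicate 1). The TOR signalling median turned to 0.02 without BP12-2 replicate 3 or WT replicate 3. For other organs, shoot meristem and young leaf markers had a median of 0.11 (adjusted p = 0.464), 5 floral markers 0.00 (0.821) and the 2 measured seed storage genes 0.69 (0.0810). CLV1 was at 128 ± 21.7 and 111 ± 6.83 CPM, SVP at 43.6 ± 9.47 and 46.7 ± 7.99 CPM and OLEO4 at 4.31 ± 0.48 and 3.31 ± 0.42 CPM. The seed storage median was 1.13 without WT replicate 1 and 0.42 without WT replicate 2. The floral median was -0.18 without BP12-2 replicate 1 and 0.55 without WT replicate 3, and the meristem median 0.00 without BP12-2 replicate 3. Genes encoded in the chloroplast and mitochondrial genomes had 0 members in the count table.

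Of the 600 list members tested, 0 passed the edgeR quasi-likelihood test over all genes, 155 had an unadjusted p under 0.05, and 52 passed with the edgeR exact test, 46 with DESeq2 and 0 with limma voom. Over all 19436 genes kept by the filter, 13 passed the quasi-likelihood test and 3544 had an unadjusted p under 0.05. The exact test passed 841 genes, DESeq2 622 and limma voom 22.

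The circadian clock list did not pass between the genotypes (13 members, median 0.15, camera adjusted p = 0.936; median -0.43 without BP12-2 replicate 1 and 0.33 without WT replicate 3), and its genes set 1 library of each genotype apart from the rest. LHY, a morning-phased clock gene, was at 23.2 CPM in BP12-2 replicate 1 and 27.0 CPM in WT replicate 3, and between 140 and 193 CPM in the other 4 libraries. PRR5, which peaks later in the day, was at 26.2 and 37.5 CPM in these 2 libraries and between 2.01 and 3.16 CPM in the other 4. GRP7 was at 416 and 391 CPM against 74.7 to 144 CPM, and GI at 149 and 158 CPM against 62.3 to 74.8 CPM. CCA1 was at 124 and 102 CPM against 154 to 241 CPM.

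**Figure D3:**
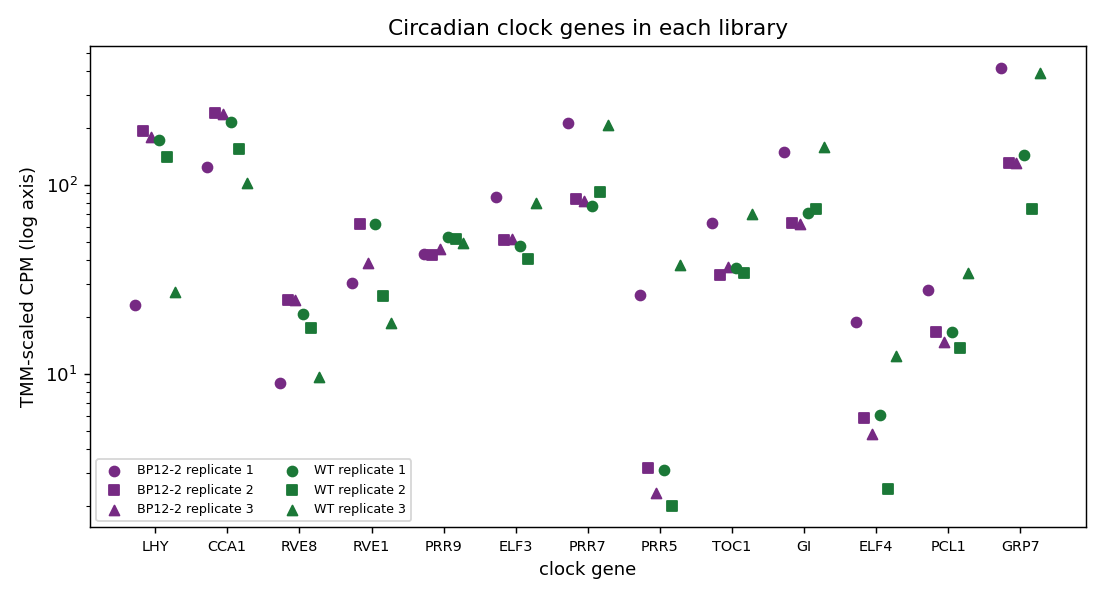
TMM-scaled CPM (log axis) of 13 circadian clock genes in each of the 6 libraries, purple for BP12-2 and green for WT, with the marker shape giving the replicate. BP12-2 replicate 1 and WT replicate 3 lie together, at 23.2 and 27.0 CPM for LHY and at 26.2 and 37.5 CPM for PRR5.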

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

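The clock-pattern and offset settings here were chosen after seeing the data; the others were fixed before. Against 13 genes in the main test, DESeq2 gave 622 (279 higher, 343 lower), the edgeR exact test 841 (398 higher, 443 lower), limma voom 22, no filter 56 and a threshold of 0.01 gave 1. RLE, upper-quartile factors and removal of ribosomal RNA genes gave 13. Leaving out each library in turn gave 0 to 56 genes, the 56 (32 higher, 24 lower) without WT replicate 1. All 13 genes passed with DESeq2, the exact test, voom, each scaling and each filter, and kept their sign in every setting. Of the 13, 9 passed in the 4 libraries of one clock pattern and 0 with the replicate block. Without BP12-2 replicates 1, 2 and 3 in turn 4, 1 and 0 passed, and without WT replicates 1, 2 and 3 in turn 12, 1 and 2. A term for the clock pattern gave 992 genes (489 higher, 503 lower), 1150 with DESeq2 and 881 with GC and length offsets, and the 4 libraries of one pattern gave 41. In the simulated counts with a difference between the marked libraries and the rest, the quasi-likelihood test recovered 39% of genes changed 2-fold. The exact test recovered 66%, DESeq2 67% and the quasi-likelihood test with the clock-pattern term 66%. Their false calls were 12, 9 and 8, against 1. The simulated spread came from the fit with that term. How far such differences account for the counts here was not tested. The cause of the differences between filters and between left-out libraries was not tested either, and 0.01 is a stricter limit.

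The replicate block gave 0 genes (3544 had an unadjusted p under 0.05 without it) and 18 lists. Same-numbered libraries deviated from their group means with correlations of -0.31, 0.06 and -0.30 across genes. No BP12-2 library correlated best with the WT library of its own number. Deviations within a group sum to 0, so the correlation of 0.47 between BP12-2 replicate 1 and WT replicate 3 lowers the others. These values therefore cannot exclude that equal numbers pair samples.

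Of 17 lists past camera, 0 passed with an estimated correlation and 0 passed fry, with adjusted p of 0.0914 or more. The 1 list past fry, expansins and primary wall (adjusted p = 0.00366), did not pass camera (adjusted p = 0.153). Leaving out a library gave 13 to 19 lists. The cytosolic ribosomal protein median turned from -0.09 to 0.03 in the 4 libraries of one clock pattern and ran from -0.18 to 0.04 with a library left out; the cause was not tested. The TOR transcript did not pass in any setting run (adjusted p from 0.181 to 0.645), with log2 fold changes from -0.26 to -0.10. Alternatives for normalized values or for a table of the authors' comparisons were not run, since the values are counts. Removal of organelle genes removed none.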

Other observations

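The tests of clock phase and depth, of root markers, touch genes and column codes, and the splits of the main count were chosen after the results were seen, as were the gene families and genes named here. More gene families passed camera with the preset correlation than are described, among them photosystem I subunits (median 0.39) and nuclear RNA polymerase (median -0.45). Among 372 families by annotated product, 10 proline-rich extensin-like genes had a median log2 fold change of 0.80 (camera adjusted p = 1.24e-04; adjusted p = 0.809 with an estimated correlation) and 13 root hair specific genes 0.52 (adjusted p = 6.61e-04; adjusted p = 0.849 with an estimated correlation). Laccases, enzymes of lignin polymerisation, had a median of 0.30 over 13 genes (adjusted p = 0.00175; adjusted p = 0.809 with an estimated correlation). The 43 genes annotated as WRKY DNA-binding had a median of -0.36 (adjusted p = 3.07e-04; adjusted p = 0.809 with an estimated correlation), and the 10 annotated as WRKY family transcription factor, which did not pass, a median of -0.25 (adjusted p = 0.123).

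With the clock-pattern term, whose marked libraries were picked from these same data, the edgeR quasi-likelihood test passed genes that missed its threshold without it, among them the 4 named here. Without the term these 4 also missed with limma voom (adjusted p of 0.0718 to 0.0919) and passed with the edgeR exact test (6.00e-07 to 0.00236) and DESeq2 (3.78e-06 to 0.00330). JAL22, a jacalin-related lectin gene, had a log2 fold change of 2.65 ± 0.37 (SE, edgeR adjusted p = 0.0183), against an adjusted p of 0.0826 without the term. GA3OX2, an enzyme of gibberellin synthesis, had 2.12 ± 0.29 (adjusted p = 0.0183; 0.0949 without the term) and the expansin EXPA8 1.59 ± 0.21 (adjusted p = 0.0175; 0.103 without the term). GAD4, a glutamate decarboxylase gene, had -1.84 ± 0.16 (adjusted p = 0.00899; 0.0693 without the term). In the 4 libraries of one clock pattern GAD4 passed (adjusted p = 0.0277), while JAL22 (0.0666), GA3OX2 (0.0713) and EXPA8 (0.0739) did not.

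BP12-2 replicate 1 and WT replicate 3 deviated together from their groups, with a correlation of 0.47 across genes, which are not independent replicates. Of the 13 measured clock genes, 11 were chosen for the test after their values were seen, and these 11 went in the direction of their class in both libraries, with LHY, CCA1, RVE8 and RVE1 lower and PRR7, PRR5, TOC1, GI, ELF4, PCL1 and GRP7 higher. PRR9, left out of the 11, deviated by -0.02 and -0.08 on the log2 scale and ELF3 by 0.74 and 0.86, so harvest at another time of day stays a candidate explanation. The totals of both libraries (2 of 2) lay within the range of the other 4, which argues against depth; harvest times are not given in the sources used here. Marking each of the other 8 pairs of a BP12-2 and a WT library gave 1 to 16 genes between the genotypes, against 992 for this pair. This pair was picked from the same data and has the highest correlation of deviations. A term for it can take up shared spread. The coefficient of variation was 11.7% with the term against 16.3% in the main fit. How far the higher count comes from the choice of the pair was not tested, so the count decides on no explanation.

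Photosynthesis genes were higher in BP12-2, with a median log2 fold change of 0.31 over 62 genes (adjusted p = 0.490 for each of the 3 lists with an estimated correlation). GC or length bias as the whole cause is argued against by a median of 0.25 after the offsets. In the 4 libraries of one clock pattern the median was 0.26. The other pattern holds 1 library of each genotype, so it was balanced between the groups and the median could hardly have fallen. That test therefore does not decide on clock phase, and smaller differences in phase among the 4 libraries were not tested. A larger share of shoot tissue would lower root markers, whose median was 0.26 (camera adjusted p = 2.04e-04; adjusted p = 0.567 with an estimated correlation), although WT replicate 1 lay at the level of BP12-2. The genotype stays open as an untested biological explanation, as does a batch marked by the column codes.

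Wounding and salicylate genes were lower in BP12-2, with a median of -0.90 over 31 genes (adjusted p = 0.490 for both lists with an estimated correlation), and -0.96 after the offsets, which argues against GC or length bias. Handling at harvest may contribute: the touch genes TCH2, TCH3 and TCH4 had a median of -0.75, but TCH3 alone passed adjusted over the list alone and all 3 belong to the list, which keeps this open, as does WT replicate 2, whose wounding median (-0.12) lay nearer to BP12-2 replicate 1 (-0.29) than to the other WT libraries (0.78 and 0.69). Of the groups, 0 carry both column codes L07 and L08, so a sequencing batch marked by them cannot be told apart from the genotype. The genotype stays open as well.

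For the count of genes, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many as the 13 genes of the real split, which is the real split itself, and the highest other split gave 1. With the clock-pattern term, 1 of 6 splits that keep the 2 marked libraries apart gave as many as the 992 genes of the real split, and the highest other gave 0. These splits are too few for a share under 0.05.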
